A study of Triticum aestivum with 12 samples.

How the data were processed

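Gene expression was measured by sequencing of polyA RNA from leaves of bread wheat (Triticum aestivum, a hexaploid with the subgenomes A, B and D), variety Chinese Spring L42. The labels assign 12 libraries to 4 groups of 3: full irrigation or drought, each sprayed with water or with LRM, a biostimulant made from microalgae. Fully irrigated pots received 180 ml and drought pots 30 ml at each of 2 waterings a week, in pots that retained 180 ml. LRM was sprayed on the leaves at 0.5% from the day after planting and again at intervals of 14 days, per the labels. Neither the age of the plants at harvest nor the water status of the leaves is given in the sources used here. The labels number the libraries of each group but do not say that they came from separate plants, so p-values measure the spread between these samples, part of which may be technical.

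The deposited count table holds whole-number read counts for 99386 gene identifiers, and 75198 of them have at least 1 count. The submitters' processing notes name FastQC, HISAT2, StringTie and DESeq2, without versions or roles. The genome build, the annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Wheat genes mostly exist as near-identical copies on the A, B and D chromosomes, so the counts of a named gene may include reads of a copy, and each named gene is uncertain in that respect.

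The authors also deposited a second table whose values are FPKM, as judged from the values, since no header names the unit. For 99.8% of the 555204 cells with more than 20 counts, the FPKM lay within 5% of the value that the count, the library total and a constant length per gene imply. Among these cells 176 were whole numbers of 100 or more, and 173 of those, in 171 genes, were 1000 times the implied value within 5%. In irrigated_LRM 3, Traes_7BL_369527295 had an FPKM of 314931 against 285 to 418 in the other 11 libraries, and its 2153 counts imply 315. The FPKM table was therefore used only for alternatives, as deposited and with such cells divided by 1000. Some cells beyond these 173 were divided too: 12 to 23 cells per library were divided, against 7 to 19 per library among the 173.

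Total counts per library ran from 17541561 to 47305447. The self-check on precision was a simulation of counts for the 57226 tested genes from their means, library sizes and dispersions, in which 200 genes were changed. For drought against full irrigation in water-sprayed plants, edgeR found 44.8% of the tested 2-fold changes and 74.6% of the 4-fold changes, and 9 of the 88 calls were false. For LRM against water in irrigated plants it found 32.3% of the 2-fold and 75.4% of the 4-fold changes, with 11 false among 81 calls. For the interaction the shares were 13.4% and 63.5%, with 2 false among 51 calls. In 4 of the 5 comparisons the share of false calls was above the nominal 5%. Changes of 1.5-fold were found in 3.03%, 0% and 0% of cases in these comparisons.

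Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM normalization and the filterByExpr filter, which left 57226 genes. All 12 libraries entered a single fit of 4 group means, and 5 contrasts were drawn from it: drought against full irrigation under each spray, LRM against water under each irrigation, and the difference of these (the interaction). A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The tests of the 5 contrasts, of agreement and of subgenomes, the first set of alternatives and the rule for named genes were fixed before the data were examined. The drought axis, the sets of abundant and co-varying genes and the tests by chromosome arm were chosen after the data were seen. Standard errors (SE) of log2 fold changes were derived from the test's F value, and CPM values are TMM-scaled, given as mean ± SD over 3 libraries. Where a whole group was at 0, a lower bound of the fold is given against 3 counts over that group. Bounds of this kind cover counting error only.

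As no identifier had a name, the rule for named genes took, per contrast, the 2 identifiers that rose most and the 2 that fell most among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. The interaction was not asked for that separation. Where fewer than 4 genes passed, the 4 with the smallest p are given as values. The identifiers carry the chromosome arm but no name, the files do not pair them with names, and 0 of them matched the gene table of assembly IWGSC CS RefSeq v2.1. For that reason the 38 lists of pathway and marker genes fixed beforehand could not be applied, and genes are described by identifier, arm and subgenome.

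Agreement between contrasts was measured as correlations of log2 fold changes across genes, which are not independent replicates, and as overlaps of calls beside the number expected for independent lists. A drought axis was drawn through the means of the irrigated and drought groups of 1 spray, in log2 CPM over the genes called there, with the irrigated mean at 0 and the drought mean at 1. Libraries of the other spray were projected on it and compared by exact permutation tests. Calls per subgenome and per chromosome arm were compared with the other genes by Fisher's exact test, adjusted over 36 and 246 tests. Fisher's test takes genes as independent, which copies and genes that vary together are not, so its p-values measure no spread between libraries.

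Alternatives included DESeq2 1.42.0, other scalings and filters, a replicate block, limma 3.58.1 on log2 FPKM with a pseudocount of 1 or 0.1, fits to the 2 groups compared, and the omission of each library. Alternatives chosen after the data were seen removed a trend with gene length (implied lengths were known for 94.0% of tested genes), thinned all libraries to the smallest total, or corrected for a set of co-varying genes. Figures were drawn with matplotlib.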

Results

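Leaves of bread wheat were profiled under full irrigation or drought, with water or the microalgal biostimulant LRM sprayed on the foliage, in 3 libraries per group. Total counts were 32655769 to 44596075 in irrigated_water, 39432162 to 47305447 in drought_water, 31381925 to 41695671 in irrigated_LRM and 17541561 to 42569702 in drought_LRM, where replicate 2 was the shallowest library. The comparisons ask what drought changed under each spray, and what LRM changed in drought-stressed and in fully irrigated plants. The first principal component held 35.9% of the variance of log2 CPM, and the 3 drought_LRM libraries had its highest scores. Spearman correlations ran from 0.957 to 0.978 within groups and from 0.915 to 0.979 between groups. The libraries irrigated_water 1, irrigated_LRM 1 and drought_LRM 2 had the highest share of their group of a set of 14 co-varying genes, chosen after their values were seen, at 0.488%, 0.353% and 3.02% of counts. With these 3 libraries left out, edgeR called 109 genes for drought with water, 8264 for drought with LRM, 5045 for LRM under drought and 12 for the interaction. No pair of replicates agreed within sampling noise, as chi-square per degree of freedom was 4.17 or more.

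**Figure D1:**
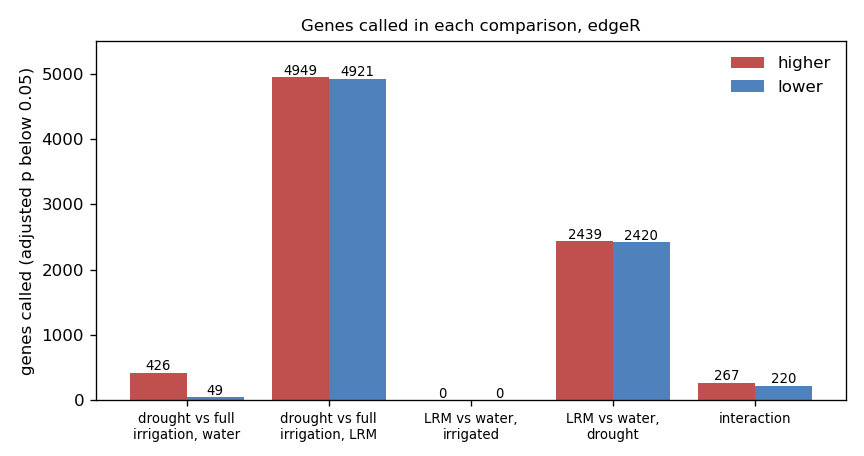
Number of genes called higher and lower in each of the 5 comparisons by edgeR (adjusted p below 0.05, 57226 genes tested). The bars for drought with LRM reach 4949 and 4921 genes, against 426 and 49 with water, and LRM under full irrigation has 0.

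In water-sprayed plants most of the genes that passed the test of drought were higher. edgeR called 475 genes, of which 426 were higher and 49 lower under drought, and 307 changed at least 2-fold. Traes_4DS_656B93262 had 0 counts in the irrigated_water libraries and 28.5 ± 23.9 CPM (SD, n = 3) in drought_water, at least 1020-fold higher (adjusted p = 0.00103 by edgeR). Traes_4BS_90B7D3855 went from 0 counts to 13.6 ± 13.1 CPM (SD, n = 3), at least 488-fold higher (edgeR adjusted p = 0.0141). Both transcripts differed widely among the drought_water libraries: Traes_4DS_656B93262 stood at 53.9, 25.1 and 6.57 CPM in replicates 1, 2 and 3. Traes_3AS_8A727B48F fell from 40.2 ± 3.22 to 11.5 ± 7.41 CPM, a log2 change of -1.81 (SE 0.31, edgeR adjusted p = 0.0141). Traes_4DL_D7237EFB9 fell from 264 ± 92.5 to 119 ± 22.0 CPM, a log2 change of -1.15 (SE 0.25, edgeR adjusted p = 0.0453). The count was 225, 110 and 148 genes without irrigated_water 1, 2 or 3, 154 and 170 without drought_water 1 or 2, 983 without drought_water 3, and 1129 by DESeq2. Genes called lower numbered 29, 3 and 11 without irrigated_water 1, 2 or 3, and 8, 5 and 186 without drought_water 1, 2 or 3. DESeq2 called 828 higher and 301 lower. Of 21 alternatives by edgeR, DESeq2 or limma, Traes_4DS_656B93262 lost its call in 0 (adjusted p up to 0.0498), Traes_4BS_90B7D3855 in 6 (up to 0.151; among them without irrigated_water 2 or 3), Traes_3AS_8A727B48F in 6 (up to 0.0961; among them without irrigated_water 2 or 3 or drought_water 2) and Traes_4DL_D7237EFB9 in 13 (up to 0.331; among them by library totals, limma, a fit of the 2 groups, or without irrigated_water 1 or 2 or drought_water 1 or 2).

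In LRM-sprayed plants drought changed 9870 genes, 17.2% of those tested, in both directions. Of these 4949 were higher and 4921 lower, with median log2 changes of 0.95 and -0.76, and 3886 changed at least 2-fold. Traes_4AL_02F7D1B1F rose from 0 counts in irrigated_LRM to 111 ± 15.3 CPM (SD, n = 3) in drought_LRM, at least 3957-fold (edgeR adjusted p = 6.86e-06). Traes_4BS_90B7D3855, also among the genes that rose most with water, went from 0 counts to 88.0 ± 8.60 CPM, at least 3126-fold (edgeR adjusted p = 0.000137). These genes and Traes_4DS_656B93262 lie on chromosomes 4A, 4B and 4D. They may be copies of a single gene, which was not tested. Traes_5AS_8DF82307C3 fell from 6.75 ± 2.89 to 0.120 ± 0.0341 CPM, a log2 change of -5.73 (SE 0.43, edgeR adjusted p = 3.32e-06). Traes_5AS_8DF82307C2 had nearly the same counts and fell by 5.70 on the log2 scale, and the pair may share reads, so that they are uncertain as separate genes. These 4 calls held in 21 of 21 alternatives each, with adjusted p of at most 0.00201 by edgeR, DESeq2 or limma. Scaling by library totals in place of TMM shifted the median of all genes by 0.16 on the log2 scale and moved the calls to 6800 higher and 2937 lower, so the even split is relative to the bulk of genes under TMM.

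Under full irrigation no gene passed the test of LRM against water: edgeR called 0 genes, with 4977 genes (8.70%) at an unadjusted p below 0.05, while DESeq2 called 211 and limma on log2(FPKM + 1) called 0, or 3 without its filter. The 4 genes with the smallest p had an edgeR adjusted p of 0.319 each. Traes_2DL_07D8661A5 had 0 counts in irrigated_water and 48 over the irrigated_LRM libraries (0.455 ± 0.149 CPM). Traes_2BL_F720DFCDE had 80 counts in irrigated_water (0.733 ± 0.171 CPM), Traes_7BL_EDE0B195F 46 (0.413 ± 0.170 CPM) and Traes_3DL_B4379510B 32 (0.298 ± 0.0120 CPM), and all of these had 0 in irrigated_LRM. Omission of irrigated_water 1 gave 3 calls and that of irrigated_LRM 3 gave 2.

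Under drought LRM-sprayed leaves differed from water-sprayed leaves in 4859 genes, 2439 higher and 2420 lower, of which 1637 changed at least 2-fold. Traes_7DL_AC271F4EE had 28.5 ± 9.44 CPM (SD, n = 3) in drought_LRM against 0.659 ± 1.14 in drought_water, a log2 difference of 5.37 (SE 0.85, edgeR adjusted p = 0.00514). Traes_7AL_40678A3B5 had 14.5 ± 8.00 against 0.201 ± 0.347 CPM, a log2 difference of 6.09 (SE 0.80, edgeR adjusted p = 0.00225). Both had counts in drought_water 1 alone among the drought_water libraries and 0 in every irrigated library. The library drought_water 1 thus sets their differences, which were fitted at 13.03 and 12.06 without it, against a group at 0. As they lie on chromosomes 7D and 7A, they may be copies of a single gene, which was not tested. Traes_2DS_CE7A57AB0 was lower with LRM, at 0.430 ± 0.745 against 6.56 ± 3.11 CPM, with a log2 difference of -4.71 (SE 0.82, edgeR adjusted p = 0.00388). Its 24 counts in drought_LRM were all in drought_LRM 2, which sets that value, and without it the difference was fitted at -11.00 against a group at 0. Traes_7DL_630534A5F was at 2.70 ± 0.916 against 14.7 ± 2.95 CPM, a log2 difference of -2.47 (SE 0.25, edgeR adjusted p = 0.000606), and it kept its call in 21 of 21 alternatives. The count was 2594 without drought_water 2, 1739 without drought_water 3 and 2845 without drought_LRM 1, and with library totals 3081 calls were higher and 1541 lower, as the median of all genes moved by 0.11 on the log2 scale. DESeq2 did not call Traes_7AL_40678A3B5, Traes_7DL_AC271F4EE or Traes_2DS_CE7A57AB0, whose adjusted p over edgeR, DESeq2 and limma alternatives ran from 0.000164 to 0.345, from 8.27e-05 to 0.489 and from 0.00111 to 0.0574.

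The interaction, the test of whether drought changed a gene differently under the sprays, called 487 genes. The interaction was positive in 267 genes, all of which were called higher under drought with LRM, and negative in 220, of which 217 were called lower with LRM. This overlap is largely built in, since the interaction contains the drought change with LRM and shares its libraries. Traes_2BS_10ADACF65 went from 0.305 ± 0.0513 to 10.5 ± 3.15 CPM with LRM and from 0.715 ± 0.469 to 1.63 ± 0.663 CPM with water, an interaction of 3.90 on the log2 scale (SE 0.64, edgeR adjusted p = 0.0223). For Traes_3B_9F3320C78 the interaction was 3.58 (SE 0.69, edgeR adjusted p = 0.0337), with 5.16 ± 1.40 CPM in drought_LRM and 0.585 ± 0.325 in drought_water. The pair Traes_5AS_8DF82307C3 and Traes_5AS_8DF82307C2 had interactions of -3.98 (SE 0.57) and -3.93 (SE 0.57), each with an edgeR adjusted p of 0.016. With water they fell from 2.91 ± 0.384 and 2.89 ± 0.379 to 0.856 ± 0.231 and 0.842 ± 0.242 CPM (edgeR adjusted p = 0.019 and 0.0188). In irrigated leaves the LRM-sprayed level of 6.75 and 6.59 CPM differed from the water-sprayed level by 1.21 and 1.19 on the log2 scale (edgeR adjusted p = 0.383 and 0.393), which enters the interaction. The count was 20 without irrigated_water 2, 27 without drought_water 2, 36 without irrigated_LRM 2, 42 without irrigated_LRM 1, 103 without irrigated_LRM 3, 142 without drought_LRM 2, 179 and 184 without irrigated_water 1 or 3, 199 without drought_water 3, 241 without drought_LRM 1, 1295 without drought_water 1 and 1731 by DESeq2. Of 26 alternatives Traes_2BS_10ADACF65 lost its call in 7, Traes_3B_9F3320C78 in 11 and the 5AS pair in 2 each: all 4 without irrigated_water 2, Traes_2BS_10ADACF65 also without irrigated_water 3, drought_water 2 or any irrigated_LRM library, and Traes_3B_9F3320C78 without any library but drought_water 1 and drought_LRM 2. With library totals 346 calls were higher and 182 lower, as the median of all genes moved by 0.11 on the log2 scale.

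The drought responses under the sprays, measured in separate libraries, shared their direction. Of the 426 genes higher with water, 397 were called higher with LRM (36.8 for independent lists), and of the 49 lower genes 43 were called lower (4.21 for independent lists). Across all tested genes the log2 changes correlated with r = 0.50 (Spearman 0.44), and r was 0.85 over the 18235 genes with a mean of at least 5 CPM. Without drought_water 1 the value over all tested genes was 0.34. Among the 475 genes called with water the median log2 change was 1.16 with water and 2.08 with LRM. Of the 9870 genes called with LRM, 89.1% had the same sign with water, and 32 had the other sign at an unadjusted p below 0.05. The share with the same sign was 90.1% for the 4949 higher and 88.1% for the 4921 lower genes. The mostly higher calls with water thus describe the genes that passed the threshold there.

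**Figure D2:**
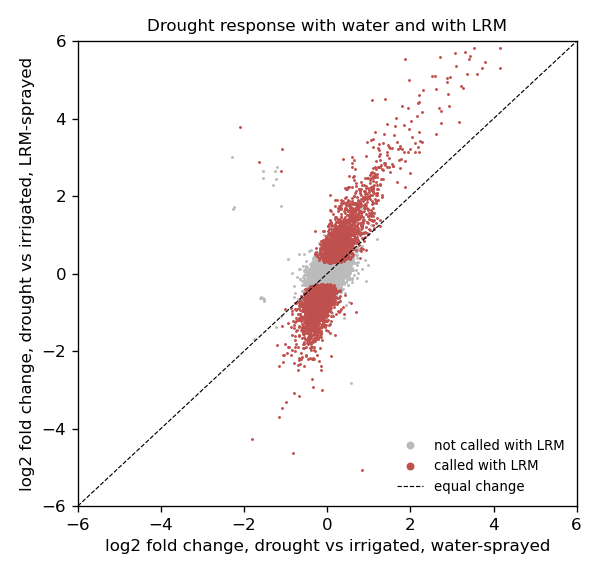
Log2 fold change of drought against full irrigation in water-sprayed plants (x axis) and LRM-sprayed plants (y axis) for the 18235 genes with a mean of at least 5 CPM, 52 of which lie outside the axes. Red points are genes called with LRM, grey points the others and the dashed line equal change; most red points lie farther from 0 on the y axis than on the x axis, with r = 0.85.

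On the drought axis drawn from the 9870 genes of LRM-sprayed plants, the drought_water libraries stood at 0.61, 0.44 and 0.25 (mean 0.436 ± 0.178, SD, n = 3), between the irrigated_water libraries at 0.14, 0.03 and 0.03 and the drought_LRM mean at 1. The exact two-sided permutation p between drought_water and irrigated_water (n = 3 each) was 0.1, the smallest that 3 against 3 allows. LRM libraries held out of the making of the axis stood at 0.93, 0.92 and 0.85 for drought_LRM and at 0.11, -0.0037 and 0.097 for irrigated_LRM. On the axis of the 475 genes of water-sprayed plants, the drought_LRM libraries stood at 1.56 ± 0.0442 (SD, n = 3) and the irrigated_LRM libraries at -0.0143 ± 0.0294, with the same exact p of 0.1 (n = 3 each).

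**Figure D3:**
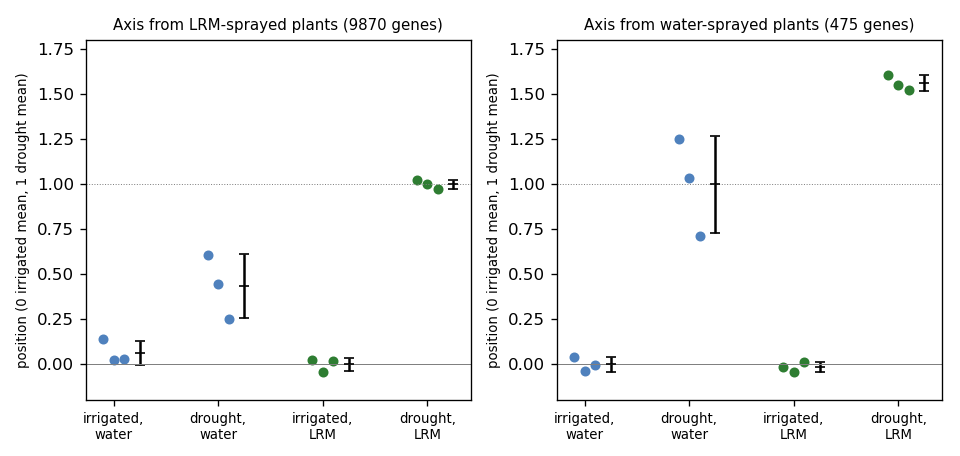
Position of each library on the drought axis drawn from LRM-sprayed plants (left, 9870 genes) and from water-sprayed plants (right, 475 genes), where 0 is the irrigated mean and 1 the drought mean of the spray that defines it. Points are libraries and bars the mean ± SD of 3; drought_water lies at 0.25 to 0.61 on the left and drought_LRM at 1.52 to 1.61 on the right.

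Of the 4859 genes that differed between sprays under drought, 63.6% had the same sign under full irrigation, and the slope of the irrigated on the drought change was 0.04. The log2 changes of LRM under both irrigations correlated with r = 0.06 across all tested genes, -0.01 without irrigated_LRM 1, and r = 0.20 over those with a mean of at least 5 CPM. Genes that drought changed with water mostly lay farther from the irrigated level with LRM: of the 426 genes that drought raised with water, 318 were higher again with LRM under drought (18.2 for independent lists), and of the 49 that it lowered 24 were lower again (2.07). These contrasts share the drought_water libraries, which alone give a negative covariance. The observed covariance of 0.0616 stood beside -0.0944 ± 0.00308 (SD) in 10 simulations without effects, and over genes with a mean of at least 5 CPM it was 0.112 beside -0.0144. Without drought_water 1, 2 or 3 the covariance over all tested genes was -0.0495, 0.00868 and -0.00778. Simulations without drought_water 1 gave -0.156, and the omission of drought_water 2 or 3 was not simulated.

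Of the 100 genes most abundant in irrigated_water, 60 fell and 1 rose under drought with LRM, with a median log2 change of -0.40. With water edgeR called 0 of these 100 genes, with 5 at an unadjusted p below 0.05, and the median was -0.08. DESeq2 called 68 lower and 1 higher with LRM and 2 lower with water, and the interaction called 2 by edgeR and 5 by DESeq2. With library totals the median with LRM was -0.24, with 53 lower and 2 higher. These 100 genes held 38.1% ± 0.402 of the counts in irrigated_LRM, 32% ± 1.51 in drought_LRM, 37.6% ± 2.31 in irrigated_water and 36.6% ± 1.38 in drought_water (SD, n = 3).

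No difference in calls between subgenomes passed its test. With drought and LRM 17.4% of the 18750 tested genes of subgenome D were called, against 17.2% of the others (odds ratio 1.01, 95% interval 0.966 to 1.06). The smallest adjusted p of the 36 Fisher's exact tests by subgenome was 0.963. Of 246 tests by chromosome arm 5 passed. Arm 3DS held few genes that rose under drought with LRM, 5.35% of 1065 against 8.71% elsewhere (odds ratio 0.593, Fisher's exact adjusted p = 0.00681), and few that fell, 5.07% against 8.67% (adjusted p = 0.00298). Arm 4DL also held few that rose (6.23%, adjusted p = 0.0163) and arm 6DL many that fell (11.1%, adjusted p = 0.0486). With water, 5 of the 651 tested genes of arm 5AS fell (Fisher's exact adjusted p = 0.0163), against 0.0778% of the others. Among these 5 was the named pair of 5AS genes, which may share reads. All arms together held 49 genes called lower with water, but 3 without irrigated_water 2 and 5 without drought_water 2. With so few calls the result for 5AS is uncertain, and the tests by arm were not repeated without single libraries.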

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

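The tests chosen only after the result was seen were those of depth, of a wider spread of the drought_water libraries, of a drought response carried further with LRM, and of exchanged labels over genes switched on by drought.

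The difference between the drought responses under the sprays was tested as the interaction, which called 487 genes by edgeR. The named genes with such a difference were Traes_2BS_10ADACF65 (3.90 on the log2 scale), Traes_3B_9F3320C78 (3.58), Traes_5AS_8DF82307C3 (-3.98) and Traes_5AS_8DF82307C2 (-3.93). Of 100 splits of the libraries, the real one included, 7 gave as many calls and the highest other gave 3574. A split with several times the real count points to a structure of the samples: the 15 splits that part the drought libraries by spray gave 89 to 3574 calls, and the other 85 gave 0 to 1. All 7 were among those 15, which keep the difference between the sprays under drought. The share of 7 in 100 therefore cannot decide on chance, which is not excluded for this count. The count was 20 without irrigated_water 2, 27 without drought_water 2, 36 without irrigated_LRM 2, 42 without irrigated_LRM 1, 103 without irrigated_LRM 3, 142 without drought_LRM 2, 179 and 184 without irrigated_water 1 or 3, 199 without drought_water 3, 241 without drought_LRM 1 and 1295 without drought_water 1.

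Drought changed 9870 genes with LRM and 475 with water. The 6 LRM-sprayed libraries held 0.853 times the counts of the 6 water-sprayed ones, which argues against depth, and with a trend with gene length removed the ratio of called genes was 20.7, which argues against length as the whole cause. Of the genes called with water 86.9% had a larger fitted change in the same direction with LRM (87.6% with genes at 0 put at their bounds), which a wider spread of the drought_water libraries alone would not give. Of the genes called with LRM 89.1% had the same direction with water, so a candidate explanation is a single drought response that had gone further in the LRM-sprayed plants. Whether that came from LRM, from the water left in the pots or from the time of harvest was not tested, and a difference in handling between the sprays stays open.

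The drought_water libraries lay at 0.61, 0.44 and 0.25 of the way along the drought axis. RNA of irrigated leaves mixed into drought_water 3 would lower genes switched on by drought by about a constant factor. Over 32 such genes the SD of the log2 ratio to drought_water 1 was 2.38 times the largest among pairs of drought_LRM libraries (0.623 against 0.262). These genes were chosen for at least 20 CPM in every drought_LRM library, which limits the spread of those pairs. They could hold up to 1 CPM in irrigated leaves, which a mixture would add unevenly. The wider SD goes against an even dilution of RNA like that of drought_water 1 but cannot exclude a mixture. Exchanged labels of irrigated_water 1 and drought_water 3 were tested over the genes called with LRM, and drought_water 3 differed from irrigated_water 1 in the direction of drought in 49.5% of them, under the bound of 50% set beforehand for an exchange. In the later test, 100% of 40 genes off in irrigated_LRM and on in drought_LRM were higher in drought_water 3, with medians of 3.56 CPM there and 0.355 CPM in irrigated_water 1, which an exchange would not give for these genes. With these labels exchanged edgeR called 683 genes for drought with water against 475 as labelled. With drought_water 3 merely left out it called 983, so a higher count is not particular to an exchange. The 49.5% is also what libraries close to each other on the axis would give, so it cannot decide. Of the 40 genes, 35 reached 1 CPM in drought_water 3 and 6 in irrigated_water 1, against 3 each in irrigated_water 2 and 3. Their medians were 0.195 and 0.275 CPM in irrigated_water 2 and 3, near that of irrigated_water 1. These values argue against an exchange, for these genes. Plants at different stages of drought may differ along the axis, which was not tested.

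The other comparisons have 3 libraries against 3, and their 10 splits are too few for a share under 0.05. Drought with water called 475 genes, and 2 of the 10 splits gave as many, the highest other being 683 for irrigated_water 1 with drought_water 1 and 2 against the rest, which is the exchange of labels weighed above. Drought with LRM called 9870 genes in 1 of 10 splits (highest other 2), and LRM under drought called 4859 in 1 of 10 (highest other 0, by edgeR, with 12664 genes at an unadjusted p below 0.05 in the real split). LRM under full irrigation called 0 genes by edgeR in the real split (4977 at an unadjusted p below 0.05, 211 by DESeq2), as did or exceeded 10 of 10 splits, with 1 as the highest other.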

How the results depend on the processing

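The alternatives chosen only after the data were seen were those with the length trend removed, thinned totals, decimal points restored, the co-varying genes as a covariate or 3 libraries left out, and the omission of single libraries for the correlations of the drought and of the LRM responses.

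Over the alternatives, the count of genes stayed within 1.5 times in 8 of 22 for drought with water, 21 of 22 for drought with LRM, 18 of 22 for LRM under full irrigation, 18 of 22 for LRM under drought and 10 of 27 for the interaction. For the named genes 369 values kept their direction and side of the threshold, 50 lost the threshold and 0 reversed. The cause was not tested for the changes below, except that fewer samples or genes entered where libraries, groups or small folds were left out. Drought with water called 1129 genes by DESeq2, 187 by limma on log2(FPKM + 1), 248 with a pseudocount of 0.1, 70 without the filter, 244 with decimal points restored, 109 with 3 libraries left out, 115 with only the 2 groups and 307 at 2-fold or more. Drought with LRM and LRM under drought called 3886 and 1637 at 2-fold or more. LRM under full irrigation called 211 by DESeq2 and 3 by limma without the filter, beside 0 by edgeR (4977 genes at an unadjusted p below 0.05). The interaction called 1731 by DESeq2, 870 with at least 1 CPM in 3 libraries, 307 by limma with a pseudocount of 0.1, 796 with decimal points restored and 12 with 3 libraries left out. Over genes with a mean of at least 5 CPM the drought responses correlated with r = 0.850, the LRM responses with r = 0.195, and the covariance of drought with water and LRM under drought was 0.112. By scaling with library totals the share of higher calls went from 50.1% to 69.8% for drought with LRM, from 50.2% to 66.7% for LRM under drought and from 54.8% to 65.5% for the interaction.

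Without single libraries the counts ran from 110 (irrigated_water 2) to 983 (drought_water 3) for drought with water, 6817 (irrigated_LRM 2) to 8508 (drought_LRM 2) for drought with LRM, 0 to 3 (irrigated_water 1) for LRM under full irrigation, 1739 (drought_water 3) to 5001 (drought_water 1) for LRM under drought and 20 (irrigated_water 2) to 1295 (drought_water 1) for the interaction. The correlation of the drought responses ran from 0.337 (drought_water 1) to 0.525 (drought_water 3) and that of the LRM responses from -0.0106 (irrigated_LRM 1) to 0.126 (irrigated_water 1). The covariance ran from -0.0495 (drought_water 1) to 0.0974 (irrigated_water 1), and was -0.00778 without drought_water 3.

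A replicate block gave 503, 9669, 0, 5169 and 811 calls in the order above (edgeR, where 4977 genes had an unadjusted p below 0.05 without the block for the 0), but 3 of 12 libraries correlated best with their own number, so the numbers did not pair the libraries. Among the named genes the block ended the call of Traes_4DL_D7237EFB9 (edgeR adjusted p = 0.0667, over its alternatives 0.00535 to 0.331) and no other. The alternatives for gene lists were not run, since the lists could not be applied. At these depths the simulations found 13.4% to 44.8% of 2-fold changes by edgeR.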

Other observations

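All tests of the co-varying genes were chosen only after the result was seen, as were the genes themselves.

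A set of 14 genes, chosen because they were lower under drought with water and higher with LRM, took 3.02% of the counts in drought_LRM 2, 0.261% and 0.422% in drought_LRM 1 and 3, 0.488% in irrigated_water 1, 0.353% in irrigated_LRM 1 and 0.0552% to 0.0845% in the other 7 libraries. Traes_4BS_6A4AC84DB, chosen after its values were seen, reached 9549 CPM in drought_LRM 2 against 211 to 1404 CPM elsewhere. Of the 3 drought_LRM libraries 1 lay above the highest other library, irrigated_water 1, but the choice of genes asked for a high mean of irrigated_water, so an effect of drought with LRM was not excluded and stays open. RNA of fixed composition carried over from drought_LRM 2 would keep a constant ratio across the genes, and in irrigated_LRM 1 the SD of the log2 ratio was 2.42 times that in drought_LRM 1 (0.857 against 0.354). In irrigated_water 1 and drought_LRM 3 this SD was 0.327 and 0.345, near that in drought_LRM 1, so the ratio was about as constant there. In irrigated_water 1 carry-over would bring the 40 genes off in irrigated_LRM and on in drought_LRM to a median of 7.59 CPM, but the median there was 0.355 CPM, and the genes stood at a median of 0.0342 and at most 0.378 of the expected level, which argues against it. Carry-over into drought_LRM 1 and 3, RNA from another source and an effect of the groups stay open.

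In drought_LRM 2 subgenome D held 32.8% of the counts and subgenome A 31.0%, against 31.3% to 32.2% and 31.7% to 32.3% in the other 11 libraries.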
